A study of Mus musculus with 16 samples.

How the data were processed

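Quadriceps RNA of 16 mouse samples was sequenced as 75-base paired ends on an Illumina HiSeq instrument, and RNA isolation and sequencing of all samples were done at the same time, per the labels' protocols. The deposited count table held raw read counts per gene symbol; the authors used STAR and featureCounts to make it, per the labels, and FastQC, STAR and edgeR with the genome build mm10 are named in the submitters' processing notes. Their versions, the annotation and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart, and values of near-identical genes (Mt1 and Mt2, Acot1 and Acot2, the Saa, Serpina and Cyp families) are uncertain. The second deposited table held log2 values; compared with the counts they equalled log2 CPM after 1 constant per gene and 1 per library with a residual SD of 0.00131 over 6742 genes, and they served as an alternative unit. The count table held 13320 genes and 4013 blank lines without a gene, which were left out. Every gene exceeded 0.5 CPM in at least 4 libraries, so a filter had been applied before deposit, and filterByExpr removed 0 further genes. Of the symbols 12868 (96.6%) matched GENCODE M21, from which mm10 coordinates of named genes were taken.

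Groups came from the tumour label of each sample, and replicate numbers name libraries without pairing them. Total counts were 25.9 to 34.9 M per library, TMM factors 0.802 to 1.21, and the 10 most abundant genes took 18.8% to 30.1% of counts. Libraries of a group differed by at least 12.8 in chi-square per degree of freedom, so no library was taken for a repeat of another. Counting intervals are 95% intervals, floors are 3 counts over the group, and both cover counting error only.

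Before the data were examined, the tests, the 37 gene lists (25 pathways and 12 cell types), the alternatives and the rule for named genes were fixed. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM, robust quasi-likelihood fit, 1 mean per group over all 16 libraries, Benjamini-Hochberg adjustment, threshold 0.05). Lists with at least 5 measured genes, 33 of 37, were tested with camera in limma 3.58.1 on log2 CPM with prior count 2 and a preset correlation of 0.01, and again with an estimated correlation. The lists of T, B and NK cells (0 of 13 genes measured), mitochondrially encoded subunits (0 of 13), red blood cells (3 of 7) and epithelial markers (2 of 9) were not tested. Named genes were, per tumour comparison, the 6 highest and 6 lowest log2 fold changes among genes that passed, with at least 1 CPM on average, no overlap of the groups and a symbol that is not a predicted model; 6 genes fixed beforehand; and the 2 members with the smallest p of each list that passed. For the other comparisons the rule took up to 5 genes each way. Further list members follow the order of p, and some genes are not reported here. Alb, Pdgfrb and Kcnj8 in the interaction, and the circadian and polyamine genes, were picked after their values were seen.

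Alternatives fixed beforehand were RLE and upper-quartile scaling, other count filters, DESeq2 1.42.0, limma-voom, limma-trend on the deposited log2 values, other thresholds, removal of the 10 most abundant genes, fits of 8 libraries only and omission of each library. Several analyses were chosen only after results were seen. These were the removal of libraries with transcripts of other tissues (Ngp or Mki67 over 10 CPM, or Alb over 10 CPM outside the control group, which holds for splenic C26 replicates 1 and 3, control replicate 1, subcutaneous C26 replicate 4), the removal of Rn45s, the removal of GC and length trends, the list test of sham against control, the exact permutation tests of 33 list levels in 4 comparisons, the count of calls that follow the hepatocyte level (73 genes), and the weighing of patterns. The removal of libraries spared the control group for Alb, so control replicates 2, 3 and 4 stayed in, with Alb at 67.7, 24.6 and 127 CPM. For libraries set apart from their group, 431 groups were tested, with genes of 12 or fewer counts in a group left out; this scope was widened after a first pass over fewer genes. Mixing with tumour-free RNA was tested in 2 versions: the second replaced the first after its values, and approximate values of the second, had been seen, and it changed the verdicts. The pattern on endothelial markers was taken up in place of oxidative phosphorylation after the permutation p-values of all 33 lists had been seen, and its contrast with 7 other cell types replaced one with fibro-adipogenic progenitors alone, after which a lower share of muscle fibres was no longer excluded.

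The tests were tested on simulated data with 200 changed genes among 13320. For splenic C26 against sham, edgeR recovered 60% of 2-fold and 94% of 4-fold changes, with 7 unchanged genes among 161 calls, and DESeq2 recovered 71% and 99% with 30 among 200. For the difference between tumour effects edgeR recovered 32% and 82%, with 2 among 116. The simulation changed genes in a single group and gave all groups the same spread per gene. In the data 52.0% and 50.0% of genes passed in the tumour comparisons, and tumour groups varied more in some lists. These rates thus do not cover scaling under broad change or unequal spread.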

Results

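Messenger RNA of quadriceps muscle was sequenced from male CD2F1 mice that were 8 weeks old at the start. The 16 libraries formed 4 groups of 4. C26 is a mouse colon carcinoma line whose growth is accompanied by muscle wasting. In the splenic C26 group the cells were injected into the spleen, from where they spread to the liver, and the sham group was operated on and given saline. In the subcutaneous C26 group the cells were injected under the skin, and the labels do not state what the control group received. Total gene counts ranged from 25.9 to 34.9 M per library over 13320 genes, and the ribosomal RNA feature Rn45s took 0.539% to 2.28% of them. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Sham and splenic C26 libraries carried 1 title prefix and control and subcutaneous C26 libraries another, so each tumour group was compared with its own tumour-free group. On the first principal component (65.4% of variance) the 8 tumour-free libraries lay between -60.8 and -55.4. Splenic C26 replicate 1 lay at -6.31 and subcutaneous C26 replicate 3 at 6.003, and the other 6 tumour libraries lay between 64.6 and 93.3.

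The comparison of splenic C26 with sham asked how muscle transcripts differ when colon carcinoma cells seed the liver. Fbxo32, which encodes the muscle ubiquitin ligase atrogin-1, rose from 374 ± 40.1 CPM in sham to 5236 ± 1612 CPM in splenic C26 (SD, n = 4 per group). Its log2 fold change was 3.81 ± 0.30 (SE; adjusted p = 4.32e-06, edgeR quasi-likelihood test), and the gene lies on chromosome 15 from 58175879 to 58214932 (mm10, minus strand). Trim63, which encodes the ubiquitin ligase MuRF1 (chromosome 4, 134315120 to 134329629, plus strand), rose by 4.64 ± 0.40 on the log2 scale (adjusted p = 7.44e-06). Of 24 measured ubiquitin ligase and FoxO-linked atrophy genes, 19 rose, 0 fell and 5 did not pass, and 19 rose adjusted over the list alone (camera adjusted p = 2.70e-10; adjusted p = 0.447 with an estimated correlation). All 31 proteasome subunits rose, also adjusted over the list alone (adjusted p = 1.29e-12; adjusted p = 0.544 with an estimated correlation), among them Psma5 by 1.39 ± 0.17 and Psmc2 by 1.70 ± 0.23. Splenic C26 replicate 1, which stood between the tumour-free and the other tumour libraries, had a mean proteasome level of 0.39 log2 over the tumour-free libraries, against 1.39 to 1.65 in the other 3. Of 25 autophagy and lysosome genes 18 rose and 7 did not pass, with 20 higher and 2 lower adjusted over the list alone (adjusted p = 1.84e-06; adjusted p = 0.544 with an estimated correlation). The autophagosome protein gene Map1lc3b rose by 2.08 ± 0.24 and the cargo receptor gene Sqstm1 by 1.66 ± 0.19.

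**Figure D1:**
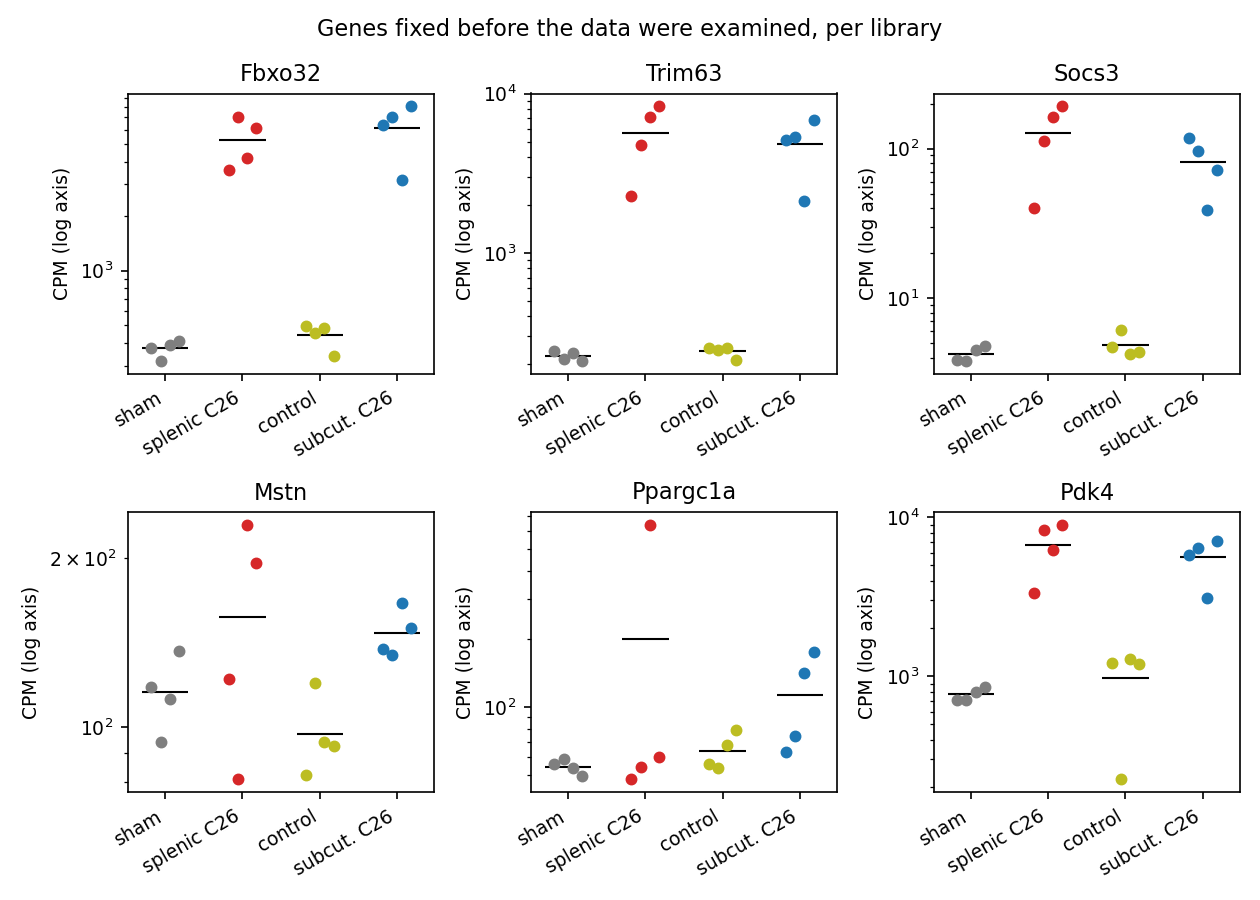
CPM of 6 genes fixed before the data were examined in each of the 16 libraries (log axis); points are libraries and bars are arithmetic group means. Fbxo32 averaged 374 CPM in sham and 5236 CPM in splenic C26, and 443 CPM in control and 6152 CPM in subcutaneous C26.

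In splenic C26, of 23 IL-6/STAT3 and acute-phase genes 20 rose and 3 did not pass, with 20 higher adjusted over the list alone (adjusted p = 5.27e-09; adjusted p = 0.447 with an estimated correlation). Hepatocyte markers, which stem from the organ that makes many acute-phase proteins, rose in 6 of 8 cases, 7 adjusted over the list alone, without passing as a list (adjusted p = 0.249). Their mean level was 2.76 in splenic C26 replicate 1 and -2.23 to -1.62 in the other 3, while the IL-6/STAT3 level was 1.95 in replicate 1 and 2.21 to 3.15 in the other 3. The IL-6 receptor gene Il6ra rose by 3.94 ± 0.35, and Socs3, a feedback inhibitor of STAT3 signalling (chromosome 11, 117966079 to 117970047), rose by 4.90 ± 0.45 (adjusted p = 1.03e-05). The iron-binding acute-phase gene Lcn2 rose from 0.844 ± 0.287 to 804 ± 1039 CPM, by 9.90 ± 1.47 on the log2 scale. It ranged from 15.5 CPM in splenic C26 replicate 1 to 2318 CPM in replicate 3, without which the log2 fold change of Lcn2, splenic C26 against sham, was 8.48 (adjusted p = 0.000393). Of 15 glucocorticoid-induced genes 14 rose, and 14 rose adjusted over the list alone (adjusted p = 6.81e-09; adjusted p = 0.447 with an estimated correlation), including Zbtb16 by 2.31 ± 0.19 and Fkbp5 by 3.88 ± 0.45. The metallothionein gene Mt2, whose reads may be shared with Mt1, rose by 8.39 ± 0.99. Of 20 genes of IGF1, insulin and mTOR signalling 13 rose and 3 fell, with 14 and 5 adjusted over the list alone (adjusted p = 0.0227; adjusted p = 0.544 with an estimated correlation). Eif4ebp1, a translation repressor, rose by 3.69 ± 0.40. Of 11 neutrophil markers 9 rose and 2 did not pass, with 10 higher adjusted over the list alone (adjusted p = 0.00759; adjusted p = 0.623 with an estimated correlation). The mean level of the list was 5.04 in splenic C26 replicate 3 and 0.64 to 2.131 in the other 3. Other blood-cell and proliferation genes were high in the same library: Slc4a1 at 17.4, Mki67 at 7.80 and Camp at 6.44 CPM, each the highest of its group, and the red blood cell markers, too few to test, rose in 3 of 3 cases. Ngp, a granule protein gene, stood at 45.8 CPM in splenic C26 replicate 3 and at most 1.05 CPM in the other splenic C26 libraries. Its group total was 1237 times that of sham (95% counting interval 222 to 48907, with 1 count in sham), and without splenic C26 replicate 3 its adjusted p was 0.136. Mpo was at least 77.3-fold and Ltf at least 74.9-fold higher, set against 3 counts over the sham group, where both were at 0. Of their 190 and 184 counts in splenic C26, 181 and 173 were in replicate 3, so these limits rest on that library.

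Ribosomal genes rose in splenic C26, and matrix and interferon-linked genes fell. Of 49 cytosolic ribosomal protein genes 47 rose and 2 did not pass, also adjusted over the list alone (adjusted p = 2.16e-12; adjusted p = 0.544 with an estimated correlation). Rpl10a rose by 1.18 ± 0.19. Of 20 ribosome biogenesis genes 18 rose and 1 fell, also adjusted over the list alone (adjusted p = 4.87e-07; adjusted p = 0.447 with an estimated correlation), with Myc at 2.23 ± 0.23. Of 16 endoplasmic reticulum chaperone and unfolded protein response genes 9 rose, also adjusted over the list alone (adjusted p = 0.00533; adjusted p = 0.544 with an estimated correlation), with Dnajb9 at 1.20 ± 0.20. Of 28 genes of fatty acid uptake and oxidation 14 rose and 14 did not pass, also adjusted over the list alone (adjusted p = 0.000416; adjusted p = 0.573 with an estimated correlation). Acot1 rose by 5.30 ± 0.49 and Acot2, a near-identical thioesterase gene, by 3.28 ± 0.30; Pdk4, which inhibits pyruvate oxidation, rose by 3.13 ± 0.46. Of 26 collagen and extracellular matrix genes 17 fell and 3 rose, with 18 lower and 3 higher adjusted over the list alone (adjusted p = 0.000170; adjusted p = 0.544 with an estimated correlation). Col6a2 changed by -2.98 ± 0.58 and Col15a1 by -1.78 ± 0.30, and the mean matrix level was -0.40 in splenic C26 replicate 1 against -1.85 to -1.64 in the other 3. Of 27 interferon-stimulated and antigen presentation genes 18 fell and 0 rose, with 19 lower adjusted over the list alone (adjusted p = 0.000170; adjusted p = 0.544 with an estimated correlation), with Usp18 at -1.53 ± 0.26. Of 10 fibro-adipogenic progenitor markers 8 fell, 9 adjusted over the list alone (adjusted p = 0.00233; adjusted p = 0.544 with an estimated correlation), and of 8 tendon cell markers 5 fell, 8 adjusted over the list alone (adjusted p = 0.00380; adjusted p = 0.544 with an estimated correlation). Of 71 oxidative phosphorylation subunits 19 fell, 1 rose and 51 did not pass, with 7 lower adjusted over the list alone (adjusted p = 0.000208; adjusted p = 0.795 with an estimated correlation). The largest falls among genes chosen by the fixed rule were in Nmrk2, a nicotinamide riboside kinase gene, at -5.75 ± 1.07, and Ankrd34a at -5.04 ± 0.72.

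Over all genes, 6931 (52.0%) passed at an adjusted p under 0.05, 3745 higher and 3186 lower in splenic C26, and 1565 and 1706 of these changed at least 2-fold. The share of calls that were higher was 54.0% and became 38.5% with upper-quartile scaling, which moved the median log2 fold change of all genes to -0.24. In exact permutations of the mean list level of 8 libraries (two-sided), 20 of 33 lists had p = 0.0286, the smallest these can give. These 20 passed after adjustment (adjusted p = 0.0471). They were the 16 lists that camera called and the NF-kB, glycolysis, fast-fibre and myogenic lists, which camera did not call. Lists at that smallest p share 1 adjusted p, which falls as more lists reach it. The pass thus depends on the number of such lists and not on each list alone. Mstn, a negative regulator of muscle mass, did not pass (0.44 ± 0.25, adjusted p = 0.141), and passed without splenic C26 replicate 2 (0.66, adjusted p = 0.0154). Ppargc1a, a coactivator of mitochondrial biogenesis, passed at 1.88 ± 0.69 (adjusted p = 0.0329), but without splenic C26 replicate 3 its value was -0.0083 (adjusted p = 0.983), and without any 1 sham library it no longer passed (1.84 to 1.93, adjusted p = 0.0583 to 0.0701). The calls of Mpo and Ltf, though not their direction, were also lost: their adjusted p without 1 sham library was 0.0532 to 0.0586 and 0.0647 to 0.0712, and without splenic C26 replicate 3 was 0.278 and 0.291.

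The comparison of subcutaneous C26 with control asked the same of a tumour under the skin. Fbxo32 rose from 443 ± 71.0 to 6152 ± 2111 CPM, a log2 fold change of 3.80 ± 0.30 (SE; adjusted p = 5.16e-06), and Trim63 rose by 4.33 ± 0.40 (adjusted p = 1.04e-05). Of the 24 ubiquitin ligase and FoxO-linked genes 20 rose, also adjusted over the list alone (adjusted p = 5.49e-10; adjusted p = 0.485 with an estimated correlation), and of the 31 proteasome subunits 30 rose, 31 adjusted over the list alone (adjusted p = 1.60e-10; adjusted p = 0.485 with an estimated correlation). Of 25 autophagy and lysosome genes 16 rose, 17 adjusted over the list alone (adjusted p = 3.49e-06; adjusted p = 0.485 with an estimated correlation), with Ulk1 at 1.73 ± 0.20. Of 23 IL-6/STAT3 and acute-phase genes 16 rose and 2 fell, with 17 and 4 adjusted over the list alone (adjusted p = 3.18e-06; adjusted p = 0.485 with an estimated correlation). Control itself varied: the list level was 1.54 in control replicate 2 and 0.12 to 0.35 in the others of its group. The member Fgb was higher in control, at 2.02 to 22.1 CPM, than in subcutaneous C26, at 0.207 to 0.796 CPM. Socs3 rose by 4.06 ± 0.43, Il6ra by 4.50 ± 0.36 and Lcn2 by 6.71 ± 1.27. Of 15 glucocorticoid-induced genes 14 rose, also adjusted over the list alone (adjusted p = 9.69e-08; adjusted p = 0.485 with an estimated correlation), with Glul at 2.61 ± 0.34. The mean glucocorticoid-induced level was 1.77 in subcutaneous C26 replicate 3 and 3.24 to 3.36 in the other 3. Of 20 IGF1, insulin and mTOR signalling genes 11 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0274; adjusted p = 0.485 with an estimated correlation). Ribosomal protein genes rose in 47 of 49 cases, also adjusted over the list alone (adjusted p = 9.90e-12; adjusted p = 0.485 with an estimated correlation), and ribosome biogenesis genes in 18 of 20, also adjusted over the list alone (adjusted p = 4.56e-08; adjusted p = 0.485 with an estimated correlation). Of 16 endoplasmic reticulum chaperone and unfolded protein response genes 11 rose, also adjusted over the list alone (adjusted p = 0.00104; adjusted p = 0.485 with an estimated correlation). The largest rises by the fixed rule included Mt2 at 7.09 ± 0.93, the chemokine gene Cxcl13 at 6.29 ± 0.77, and Mrgprg, whose group total was 289 times that of control (95% counting interval 98.6 to 1406, with 3 counts in control).

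Oxidative phosphorylation genes were lower in subcutaneous C26. Of 71 subunits 61 fell, 0 rose and 10 did not pass, with 64 lower and 1 higher adjusted over the list alone (adjusted p = 6.22e-13; adjusted p = 0.487 with an estimated correlation). Ndufc2, a complex I subunit gene, changed by -0.88 ± 0.17 and Cycs, which encodes cytochrome c, by -1.16 ± 0.23. The mean level of the list was 0.0051 in subcutaneous C26 replicate 3, close to the tumour-free libraries, and -0.99 to -0.87 in the other 3. Of 29 genes of mitochondrial biogenesis, dynamics and the citric acid cycle 14 fell and 3 rose, with 14 and 4 adjusted over the list alone (adjusted p = 0.00555; adjusted p = 0.660 with an estimated correlation). Of 12 slow-fibre contractile genes 6 fell, 7 adjusted over the list alone (adjusted p = 0.0351; adjusted p = 0.660 with an estimated correlation), with Myl2 at -3.48 ± 0.76. The mean slow-fibre level averaged -0.54 in control with an SD of 1.19, and control libraries overlapped with those of subcutaneous C26. It was -3.46 in subcutaneous C26 replicate 4 and -1.70 to -1.51 in the other 3. In the same library Slc4a1 stood at 70.2 and Mki67 at 52.3 CPM, against at most 2.45 and 2.07 in the others of its group, and Rn45s took 2.28% of counts, and the red blood cell markers, too few to test, rose in 2 of 3 cases. Of 26 collagen and matrix genes 16 fell and 2 rose, with 18 and 3 adjusted over the list alone (adjusted p = 7.47e-05; adjusted p = 0.485 with an estimated correlation), and of 27 interferon-linked genes 12 fell, 10 adjusted over the list alone (adjusted p = 0.00322; adjusted p = 0.660 with an estimated correlation). Markers of Schwann cells fell in 7 of 9 cases, 8 adjusted over the list alone (adjusted p = 0.00584; adjusted p = 0.485 with an estimated correlation). Pericyte and smooth muscle markers fell in 6 of 9 and rose in 1, also adjusted over the list alone (adjusted p = 0.0151; adjusted p = 0.485 with an estimated correlation), with Kcnj8 at -1.75 ± 0.19. Tendon cell markers fell in 6 of 8, also adjusted over the list alone (adjusted p = 0.00347; adjusted p = 0.485 with an estimated correlation), and fibro-adipogenic progenitor markers in 7 of 10 and rose in 1, with 8 and 1 adjusted over the list alone (adjusted p = 0.0274; adjusted p = 0.660 with an estimated correlation). Hepatocyte markers fell in 7 of 8 and rose in 1, also adjusted over the list alone (adjusted p = 0.00835; adjusted p = 0.485 with an estimated correlation). The fatty acid list did not pass (6 higher and 2 lower of 28, 6 and 1 adjusted over the list alone, adjusted p = 0.386), and neither did the endothelial list (1 higher and 4 lower of 11, also adjusted over the list alone, adjusted p = 0.0541). Leaving out 1 library changed some of these calls. The slow-fibre call was lost without control replicate 3 (adjusted p = 0.141), subcutaneous C26 replicate 3 (0.0795) or 4 (0.0985), and the fibro-adipogenic progenitor call without control replicate 2 (0.0591), subcutaneous C26 replicate 2 (0.0622) or 3 (0.0795). The endothelial list passed, lower, without control replicate 1 (0.0368) or 3 (0.0464), or subcutaneous C26 replicate 1 (0.0336) or 4 (0.0274). In exact permutations of the mean list level of 8 libraries (two-sided), p was 0.114 for the oxidative phosphorylation, mitochondrial biogenesis and slow-fibre lists and 0.0571 for IL-6/STAT3 genes. It was 0.0286, the smallest these can give, for 17 of 33 lists, and 0 passed after adjustment (smallest adjusted p = 0.0555). The adjusted p at that floor depends on how many lists reach it, 17 here and 20 in splenic C26. It therefore does not show weaker list effects in subcutaneous C26.

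**Figure D2:**
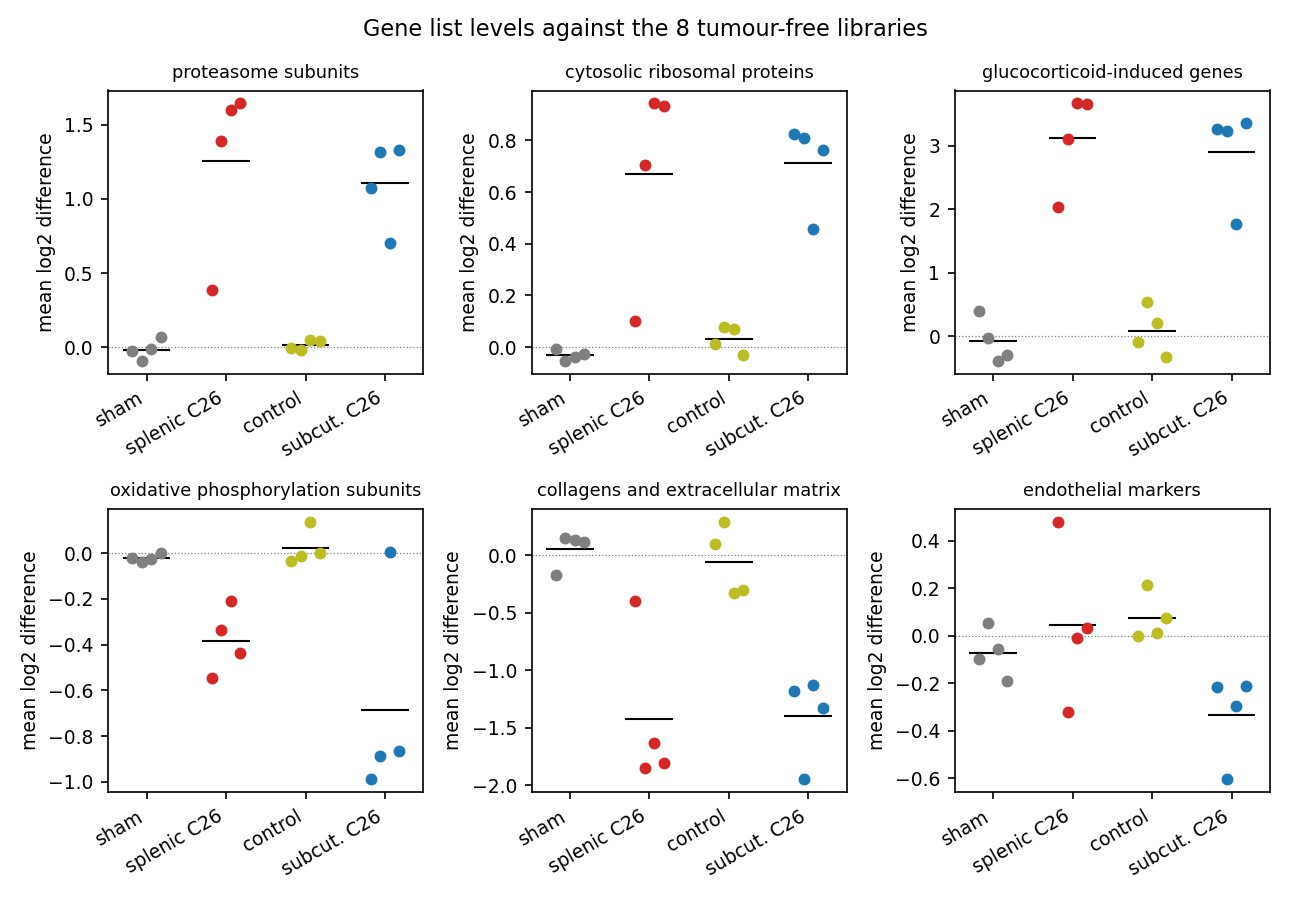
Mean log2 difference of 6 gene lists from the 8 tumour-free libraries, per library; points are libraries and bars are group means. Oxidative phosphorylation stood at 0.0051 in subcutaneous C26 replicate 3 and at -0.99 to -0.87 in the other 3 libraries of its group.

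The falls in hepatocyte genes stood beside their level in the control group. The albumin gene Alb was at 16.5 to 127 CPM in the 4 control libraries and in splenic C26 replicate 1, and at most 2.25 CPM in the 11 other libraries. Cyp2c29 and Cyp2d9 were at least 189-fold and at least 82.8-fold lower in subcutaneous C26, where both were at 0, against 3 counts over that group. A gene was taken to follow the hepatocyte level, the mean of the hepatocyte markers without Cyp2e1, if it correlated closely with it over the sham and control libraries alone. It also had to lie clearly higher in control than in sham, which held for 73 genes of 13320. Among the 3072 genes that fell in subcutaneous C26, 59 followed this level, as did 47 of the 3745 that rose in splenic C26. The choice of genes low in sham and high in control by itself favours both counts. Over all genes, 6665 passed in subcutaneous C26, 3593 higher and 3072 lower, with 1285 and 1723 at least 2-fold. The share that was higher was 53.9% and became 34.9% with upper-quartile scaling, which moved the median of all genes to -0.26. Mstn did not pass (0.60 ± 0.25, adjusted p = 0.0547), though it passed without control replicate 2 (0.70, adjusted p = 0.0470), with DESeq2 (adjusted p = 0.0454) and in the fit of 8 libraries (adjusted p = 0.00694), and Ppargc1a did not pass (0.82 ± 0.67, adjusted p = 0.319). The call of Cyp3a11 was lost without subcutaneous C26 replicate 2 (adjusted p = 0.0506) or 4 (adjusted p = 0.0538).

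The study set both tumour routes side by side, and the difference between the tumour effects was tested as an interaction. The Fbxo32 effects differed by 0.01 (95% interval -0.80 to 0.82), the Trim63 effects by 0.31 (-0.73 to 1.36) and the Socs3 effects by 0.84 (-0.32 to 2.01), all smaller than their error allowed to be told from 0. With edgeR 0 of 13320 genes passed; 851 had an unadjusted p under 0.05, where chance gives 666, the smallest adjusted p was 0.0670, and DESeq2 called 86. Without splenic C26 replicate 2 edgeR called 66 genes (1378 unadjusted), without splenic C26 replicate 1 it called 9 (2200 with an unadjusted p under 0.05), without control replicate 1 or subcutaneous C26 replicate 3 it called 4 (700 and 1568 unadjusted), and without splenic C26 replicate 4 or subcutaneous C26 replicate 4 it called 1. Kcnj8, a potassium channel gene of pericytes, had the smallest adjusted p together with Cyp26b1, with a difference of 1.65 ± 0.26, and Pdgfrb a difference of 1.13 ± 0.23 (adjusted p = 0.0983). Of the 84 genes that DESeq2 called higher, 45 followed the hepatocyte level. Such genes were chosen as higher in control than in sham, which by itself raises this difference. Of 13320 genes, the 95% interval of the difference lay within 1 log2 unit for 7386 (55.5%).

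Shared calls were frequent: 2947 genes were higher in both comparisons, where independent lists would share 1010, and 2195 were lower in both, where they would share 735. Opposite calls numbered 43, against 1723. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.703 and Spearman rho = 0.851 (jackknife standard error of r 0.119 over libraries).

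**Figure D3:**
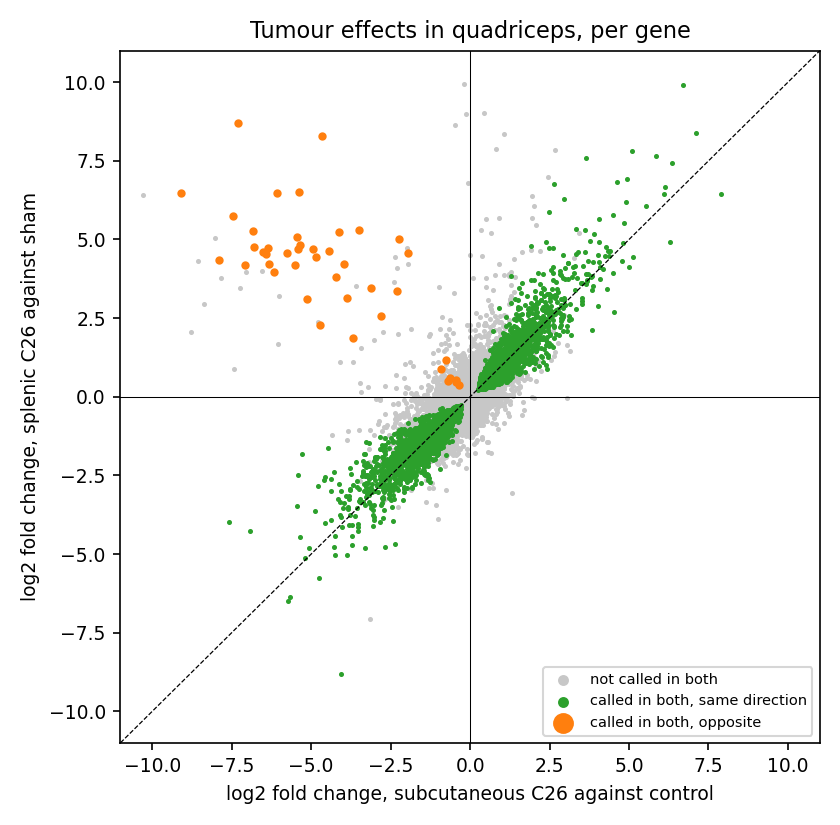
Log2 fold change of each of 13320 genes in splenic C26 against sham (vertical axis) and in subcutaneous C26 against control (horizontal axis); points are genes and the dashed line marks equal effects. Genes called in both comparisons in opposite directions number 43.

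At the level of lists, 14 of 33 passed camera with a preset correlation for this difference, and 0 with an estimated correlation. The splenic C26 effect lay above the subcutaneous C26 effect for 12 of them and below it for 2. Each effect is taken against its own tumour-free group, so this is not the direction of the level in splenic C26. Oxidative phosphorylation (adjusted p = 4.16e-15; adjusted p = 0.778 with an estimated correlation) and fatty acid genes (adjusted p = 9.11e-09; adjusted p = 0.547 with an estimated correlation) were among them, although 0 of their 71 and 28 members passed singly, also adjusted over the list alone. The endothelial list had a median difference of 0.51 (adjusted p = 1.16e-08; adjusted p = 0.470 with an estimated correlation), with 0 of 11 members passing and 5 higher adjusted over the list alone. When the mean level of each list per library was permuted exactly (4900 arrangements, two-sided), p was 0.170 for oxidative phosphorylation and 0.0122 for endothelial markers, and after adjustment over 33 lists the smallest p was 0.202. The calls of the oxidative phosphorylation, fatty acid and endothelial lists held in 16 of 16 fits without 1 library.

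Sham and control, the tumour-free groups, were compared to measure the background between them, in which the operation and the title prefix cannot be told apart. Cyp26b1, a retinoic acid-degrading enzyme gene (chromosome 6, 84571414 to 84593908, minus strand), was lower in sham, at 2.43 ± 0.51 CPM against 20.5 ± 11.2 CPM in control (log2 fold change -3.07 ± 0.40, adjusted p = 0.0138). It was the 1 gene that edgeR called of 13320. An unadjusted p under 0.05 was found for 285, or for 930 in the fit of 8 libraries, which called 0, and DESeq2 called 58. The fit of all libraries took 1 spread per gene over all groups, and tumour groups varied more in some lists, though not in every list. The SD of the proteasome level was 0.589 in splenic C26 and 0.295 in subcutaneous C26, against 0.0648 in sham and 0.0350 in control. The count from all libraries may therefore understate this background. The call of Cyp26b1 was lost without any 1 sham library (adjusted p = 0.0758 to 0.130), although the fold change stayed at -3.20 to -2.94, while edgeR called 7 genes without control replicate 1 and 4 without control replicate 3. Hepatocyte markers had a median log2 difference of -5.93 between sham and control, and although 0 of 8 passed singly, 7 were lower adjusted over the list alone (adjusted p = 3.32e-29; adjusted p = 0.00585 with an estimated correlation). Of the 50 genes DESeq2 called lower in sham, 41 followed the hepatocyte level. Those genes were chosen as lower in sham from the same libraries, so this count is no separate evidence. In all 11 of 33 lists passed with the preset correlation, 4 higher and 7 lower in sham, and 1 with an estimated correlation.

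**Figure D4:**
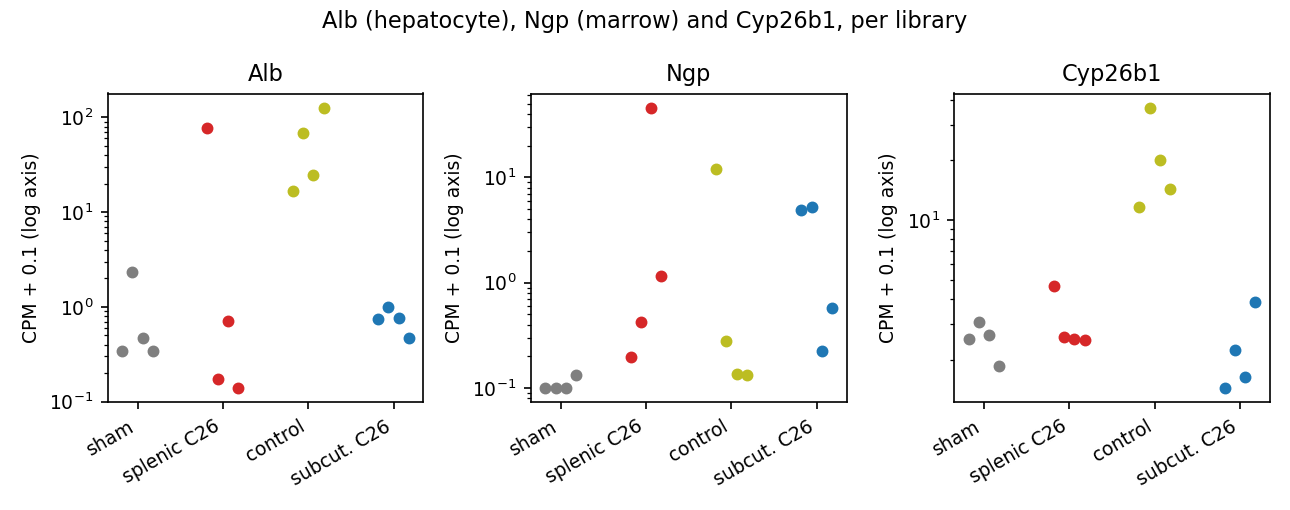
CPM plus 0.1 (log axis) of Alb, Ngp and Cyp26b1 in the 16 libraries; points are libraries. Alb lay at 16.5 to 127 CPM in the 4 control libraries and splenic C26 replicate 1, and Ngp reached 45.8 CPM in splenic C26 replicate 3.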

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

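In this part, the tests of the 3 patterns and the splits for the difference between tumour effects and for sham against control were written only after the results were seen, as was the scope of the search for libraries set apart; the splits for the other comparisons were planned. Libraries were compared with the other 3 of their group over 431 groups of gene lists, library measures and named genes. Of these 52 had a library set apart by Dixon's ratio for 4 samples, where chance, which sets apart about 1 in 20 groups, gives 21.6; 15 of the 52 were splenic C26 replicate 1 and 18 subcutaneous C26 replicate 3.

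Splenic C26 replicate 1 stood apart in mean log2 list level for ubiquitin ligase and FoxO-linked genes (1.64), collagens (-0.40), ribosome biogenesis (0.55), pericytes (-0.14) and hepatocytes (2.76). It also stood apart in log2 CPM of Psmc2 (7.61), Eif4ebp1 (7.33), Acot1 (3.28), Tnmd (2.52), Cyp2c29 (0.46), Cyp3a11 (2.79), Rps4x (7.47), Rpl7a (8.02), Dpt (6.11) and Cyp26b1 (2.21). Subcutaneous C26 replicate 3 stood apart in list level for ubiquitin ligase and FoxO-linked genes (1.65), glucocorticoid-induced genes (1.77), oxidative phosphorylation (0.0051) and cytosolic ribosomal proteins (0.46). Its log2 CPM stood apart for Mt2 (7.57), Mt1 (7.87), Aldh8a1 (-3.91), Nmrk2 (5.64), Nrep (4.46), Il6ra (5.73), Eif4ebp1 (7.51), Irs2 (6.32), Fkbp5 (8.10), Dnajb9 (6.15), Ndufc2 (6.15), Glul (10.34), Cycs (7.78) and Sirt1 (4.07).

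Among the other tumour libraries, splenic C26 replicate 3 stood apart in the myogenic list level (0.89) and in log2 CPM of Mpo (3.10) and Ppargc1a (9.32), splenic C26 replicate 4 in Ndufc2 (5.40), and subcutaneous C26 replicate 4 in the slow-fibre list level (-3.46). Among tumour-free libraries, sham replicate 1 stood apart in the levels of the circadian (0.12) and collagen (-0.17) lists, sham replicate 2 in the fast-fibre level (-0.30) and Pdgfrb (4.97), sham replicate 3 in total counts (34.9 M) and Psma5 (5.11), and sham replicate 4 in Sqstm1 (9.23). Control replicate 2 stood apart in the IL-6 list level (1.54), Pdk4 (7.81) and Pdgfrb (5.55), control replicate 3 in the NF-kB list level (-0.14), Xbp1 (6.08) and Casq2 (5.16), and control replicate 4 in Dnm1l (6.80).

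By camera with a preset correlation the tumour effects differed for 14 lists. The adjusted p was 0.0101 for proteasome subunits, 0.0155 for IL-6/STAT3 genes, 0.0445 for NF-kB targets, 4.16e-15 for oxidative phosphorylation, 0.00527 for mitochondrial biogenesis, 9.11e-09 for fatty acid genes and 0.00377 for slow-fibre genes. It was 0.00611 for macrophage markers, 0.0155 for neutrophil markers, 1.16e-08 for endothelial markers, 0.00285 for pericyte markers, 0.0481 for fibro-adipogenic progenitor markers, 0.000972 for Schwann cell markers and 1.40e-12 for hepatocyte markers. With an estimated correlation 0 of 33 passed. For IL-6/STAT3 genes the mean levels of the tumour groups were close (2.56 in splenic C26, 2.57 in subcutaneous C26). Sham stood at -0.53 and control at 0.53, so the difference of 1.05 lay in the tumour-free groups. Sham also lay below control in hepatocyte (-4.40, against a difference of effects of 5.39) and neutrophil level (-1.06 against 1.33). Sham minus control was only -0.04 for oxidative phosphorylation and for fatty acid genes, and 1.09 for slow-fibre genes. Of 16 fits without 1 library the call held in 6 for fibro-adipogenic progenitors, 9 for NF-kB targets, 12 for proteasome subunits and for IL-6/STAT3 genes, 13 for mitochondrial biogenesis, slow-fibre, macrophage and neutrophil lists, 15 for pericytes and 16 for the other 5. Without the libraries that held transcripts of other tissues, a setting chosen after the results were seen, the adjusted p was 0.221 for NF-kB targets, 0.0852 for mitochondrial biogenesis, 0.386 for neutrophils, 0.144 for pericytes and 0.132 for Schwann cells, so these 5 calls were lost. It was 1.1e-05 for ribosomal proteins, 0.000141 for autophagy, 0.000439 for collagens, 0.00361 for glucocorticoid-induced genes, 0.00901 for cell cycle genes and 0.00981 for ubiquitin ligases and for tendon markers, 7 calls gained. Ngp and Mki67, by which these libraries were partly chosen, belong to the neutrophil and cell cycle lists. Calls of these lists lost or gained in this setting can thus follow from the choice. It also left out splenic C26 replicate 1, which lay between tumour-free and other tumour libraries, but kept subcutaneous C26 replicate 3. Without splenic C26 replicate 1 alone, camera already called ribosomal proteins (adjusted p = 2.04e-07), autophagy (0.00187), collagens (0.00292) and glucocorticoid-induced genes (0.00935). Cell cycle, ubiquitin ligase and tendon lists were not gained there. Gains shared with that fit cannot be ascribed to transcripts of other tissues.

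Other splits of the same libraries were counted for each comparison. For genes in splenic C26 against sham 1 of 35 splits, the real one, gave 6931 calls and the highest other gave 2692. In subcutaneous C26 against control 1 of 35 gave 6665 and the highest other 1575. A share of 1 of 35 is the smallest these splits can give, so it argues against chance for both without excluding it. A technical grouping of the libraries was not tested. For sham against control 1 of 35 gave 1 call and the highest other 0, but a single call that was lost without any 1 sham library (adjusted p = 0.0758 to 0.130), and with 8 libraries only (adjusted p = 0.106), does not exclude chance; 285 genes had an unadjusted p under 0.05 with all libraries and 930 with 8, where chance gives 666. For the difference between tumour effects 100 of 100 splits gave at least the real count of 0, and the highest other gave 3; with a real count of 0 this could not have come out otherwise and decides nothing, and 851 genes had an unadjusted p under 0.05 (633 to 2200 without 1 library) and DESeq2 called 86. Lists called with the preset correlation were counted as well. In splenic C26 against sham 14 of 35 splits gave at least 16 lists (highest other 20), and in subcutaneous C26 against control 4 of 35 at least 19 (24). Other splits of these libraries can keep part of the tumour difference, so these counts cannot decide on chance and do not exclude it. Chance cannot be excluded for the difference, where 47 of 100 splits gave at least 14 lists (22). The same holds for sham against control, where 15 of 35 gave at least 11 (15).

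Hepatocyte transcripts stood high in the 4 control libraries and in splenic C26 replicate 1, with Alb at 16.5 to 127 CPM against at most 2.25 CPM in the 11 other libraries. Induction of Alb in muscle together with the acute-phase gene Lcn2 is argued against. Among the 3 tumour libraries with the highest Lcn2, at 417 to 2318 CPM, the highest Alb was 0.637 CPM, below every control library. The control libraries, high in Alb, held Lcn2 at only 0.872 to 4.29 CPM, and splenic C26 replicate 1 held it at 15.5 CPM. Whether an acute-phase response would raise Alb at all was not tested. The low Alb of those tumour libraries by itself therefore decides nothing. A batch that follows the title prefix is argued against, because the highest Alb among the 4 subcutaneous C26 libraries, which share that prefix, was 0.889 CPM. Carry-over of liver RNA or tissue may account for it: the ratios of 6 hepatocyte genes to Alb varied over the 5 libraries with a median SD of 0.173 of that of Alb itself. Cyp2e1, also on the hepatocyte list, was left out of this test and did not follow Alb. It stood at 15.7 to 315 CPM in the 11 other libraries and at 46.0 to 89.7 CPM in these 5. What would have brought liver material into these libraries was not tested, and the treatment of the control group stays among the open explanations.

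Splenic C26 replicate 1 and subcutaneous C26 replicate 3 lay between the tumour-free and the other tumour libraries. A tumour-free library with the wrong label is argued against, because 79.5% and 87.8% of the genes that rose at least 4-fold in the other 3 libraries of their group lay above all 8 tumour-free libraries. A first test of mixing with tumour-free RNA took the genes that fell at least 4-fold. Of these, 3.13% and 6.38% had a CPM under 0.5 of the median mixing fraction times the lowest tumour-free CPM. That fitted mixing in the first library and left the second open. A second test, chosen after the first and after approximate values were seen, replaced it. There the median fraction over risen genes exceeded that over fallen genes by 0.392 in splenic C26 replicate 1, where the other 3 libraries spanned -0.0543 to 0.508, so mixing cannot be told apart from a weaker response. In subcutaneous C26 replicate 3 the gap was 0.381 against -0.0152 to 0.0988, which argues against a single mixing fraction, and a smaller or earlier response to the tumour may account for it, which was not tested.

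The mean endothelial marker level differed between the tumour effects by 0.53 log2 (exact permutation p = 0.0122, two-sided), a pattern picked from 33 lists after all were seen, and its adjusted p was 0.202, so it did not pass and is a hypothesis only. A lower share of muscle fibres cannot be told apart: Schwann cell (0.63), pericyte (0.36) and neutrophil markers (1.33, resting on splenic C26 replicate 3 at 5.04 and control replicate 1 at 3.04) differed the same way, fibro-adipogenic progenitor (-0.57), macrophage (-0.57), adipocyte (-0.33) and tendon (-0.09) markers the opposite way, and the largest contrasts, with progenitors and macrophages (1.10 each), did not pass over 7 cell types (adjusted p = 0.110). GC content and gene length are argued against as the whole cause, since the difference was 0.55 with their trends removed. A single library is argued against for the camera call with the preset correlation, which held in 16 of 16 fits without 1 library, although it was lost with an estimated correlation (adjusted p = 0.470). A difference in muscle vessels between the tumour routes may be the cause, and so may chance or the tumour-free groups. By camera with the preset correlation sham already lay below control for endothelial (level difference -0.15, adjusted p = 0.00131) and pericyte markers (-0.31, adjusted p = 5.7e-06). Neither passed with an estimated correlation. In exact permutations p was 0.0857 for endothelial markers (adjusted p = 0.471). For pericyte markers it was 0.0286, the smallest that 8 libraries can give (adjusted p = 0.236). With 4 lists at that smallest p, no adjusted p could fall below 0.236, so these permutations cannot decide on a difference between the tumour-free groups. Mean pericyte levels of the tumour groups were close (-0.56 and -0.62).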

How the results depend on the processing

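Removal of the libraries with transcripts of other tissues, of Rn45s and of GC and length trends, and the list test of sham against control, were chosen only after the results were seen. At an adjusted p under 0.01 the calls numbered 4408 for splenic C26, 4175 for subcutaneous C26 and 0 for sham against control, and with a 2-fold change also required 3271 and 3008 for the tumour comparisons. For the difference between tumour effects DESeq2 called 86 genes, and leaving out 1 library gave 0 to 66. For sham against control DESeq2 called 58, limma-trend on the deposited values 7, the fit of 8 libraries 0 and the fit without libraries with other tissue 47, and leaving out 1 library gave 0 to 7; the cause of these shifts was not tested. With an estimated correlation the lists that passed fell to 0 in both tumour comparisons and in the difference, and to 1 for sham against control. Leaving out 1 library gave 9 to 18 lists for the difference, with 9 without splenic C26 replicate 2 or 3. Genes with an unadjusted p under 0.05 for the difference, 851 with all libraries, numbered 633 to 2200 without 1 library, and for sham against control, 285 with all libraries, 930 in the fit of 8 libraries. Calls of genes and lists in the tumour comparisons stayed within 1.5 times without 1 library: splenic C26 gave 5745 to 8201 genes and 16 to 17 lists, subcutaneous C26 5061 to 7547 genes and 18 to 21 lists, and r was 0.667 to 0.803. Ppargc1a in splenic C26 changed by -0.0083 to 2.21 without 1 library, and was near 0 with the sign turned without splenic C26 replicate 3 (adjusted p = 0.983); the cause was not tested. Of the named-gene results under settings other than leaving out 1 library, 500 of splenic C26 kept direction and side of the threshold and 12 lost the call, and 568 of subcutaneous C26 kept both, 1 lost and 2 gained it. No paired analysis was possible because the replicate numbers follow accession order and pair nothing.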

Other observations

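The genes of this part were picked after their values were seen, from lists fixed before. Circadian clock genes changed in both directions in each tumour comparison: of 19, 8 rose and 5 fell in splenic C26 (camera adjusted p = 0.329) and 8 rose and 4 fell in subcutaneous C26 (adjusted p = 0.623), so neither list passed. The clock output gene Dbp changed by -3.26 ± 0.37 in splenic C26 and -4.14 ± 0.38 in subcutaneous C26, and its repressor Nfil3 rose by 2.81 ± 0.33 and 2.45 ± 0.32. Time of collection is not given in the labels.

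Polyamine genes also moved both ways, with 4 of 8 higher and 2 lower in each comparison. Srm, which makes spermidine, rose by 1.07 ± 0.24 in splenic C26 and 1.48 ± 0.24 in subcutaneous C26, and Odc1, which makes putrescine, rose by 1.30 ± 0.31 and 1.36 ± 0.31. Smox, which oxidises spermine, changed by -2.77 ± 0.60 in subcutaneous C26. The slow myosin gene Myh7 ranged from 36.5 to 318 CPM among sham libraries and from 1.97 to 158 CPM among control libraries, in mice without tumours.

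Further lists did not pass in either tumour comparison with the preset correlation. In splenic C26 and then in subcutaneous C26, the adjusted p was 0.0796 and 0.360 for NF-kB targets (7 and 4 higher, 0 and 2 lower of 13), 0.668 and 0.887 for myostatin and TGF-beta genes (7 and 5 higher, 2 and 4 lower of 21), and 0.792 and 0.623 for ATF4 genes (9 and 7 higher, 6 and 3 lower of 21). It was 0.543 and 0.106 for glycolysis (5 and 2 higher, 6 and 6 lower of 21), 0.545 and 0.136 for fast-fibre genes (2 and 1 higher, 6 and 7 lower of 17), and 0.576 and 0.710 for myogenic and denervation genes (9 and 7 higher, 4 and 4 lower of 22). By exact permutation in splenic C26 the levels of NF-kB targets (0.56), glycolysis (-0.34), fast-fibre (-0.63) and myogenic genes (0.35) did pass (adjusted p = 0.0471). That adjusted p is shared by all 20 lists at the smallest p and depends on their number. Polyamine genes had a camera adjusted p of 0.576 and 0.709, cell cycle genes 0.249 and 0.569, macrophage markers 0.607 and 0.343, and adipocyte markers 0.921 and 0.761. Without 1 library, NF-kB targets passed in splenic C26 without replicate 2 (adjusted p = 0.0326), and glycolysis (0.0238) and fast-fibre genes (0.0180) passed in subcutaneous C26 without replicate 3. Lists that passed in 1 tumour comparison had, in the other, an adjusted p of 0.607 for slow-fibre genes, 0.216 for mitochondrial biogenesis, 0.329 for pericytes, 0.291 for Schwann cells and 0.249 for hepatocytes in splenic C26, and 0.136 for neutrophils in subcutaneous C26, where it was 0.00925 without control replicate 1. The endothelial list had 0.377 in splenic C26. Without the libraries with transcripts of other tissues, the cell cycle list passed, lower, in splenic C26 (adjusted p = 0.00970), and the neutrophil list (0.00278) passed, higher, and the endothelial list (0.0146), lower, in subcutaneous C26. In that setting, which kept control replicates 2, 3 and 4 with their hepatocyte transcripts, sham against control gained oxidative phosphorylation (0.0351) and collagens (0.0438). It lost neutrophils (0.457) and Schwann cells (0.320). The libraries left out were partly chosen by Ngp and Mki67, members of the neutrophil and cell cycle lists. Calls of these lists gained or lost there can thus follow from the choice.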
